A study of Mus musculus with 2 samples.

How the data were processed

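Tumour-draining inguinal lymph nodes of mice were studied, with 13 nodes from wild-type (WT) animals and 9 nodes from animals in which Atg5 is deleted in lymphatic endothelial cells (Atg5 LEC-KO), per the series' design text. Per the labels' protocols, the nodes were digested and the cells were stained with a viability dye and antibodies to CD45, CD31 and Ter119. Endothelial cells (CD31+, CD45-, Ter119-) and immune cells (CD45+, CD31-, Ter119-) were sorted and pooled, so that each genotype gave 1 single-cell RNA library. The ratio of endothelial to immune cells is set by the pooling of both sorts and was not compared between the libraries.

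Per the file headers, the reads were processed with the BD Rhapsody WTA Analysis Pipeline 1.11 for Enhanced beads on an mm10 reference, with refined calling of putative cells on mRNA and without sample tags, and intronic reads were not excluded. The submitters' processing notes also name mm10. Rhapsody captures transcripts at their 3' ends on barcoded beads and tags each molecule with a unique molecular identifier (UMI). The deposited files hold whole-number counts per barcode and gene for all barcodes, and no normalization had been applied to them. Each file gives reads, molecules before error correction, and molecules after the pipeline's recursive correction of substitution errors, and the last of these counts were used. The deposited tables hold all barcodes and not the called cells, so cells were called again here. Gene identifiers and coordinates were taken from a GENCODE annotation of GRCm38, the assembly also called mm10, by gene symbol, and 4 symbols of the fixed lists were matched by synonym.

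The WT library held 23649554 UMIs in 119938 barcodes from 48832612 reads, and the Atg5 LEC-KO library held 23089918 UMIs in 111135 barcodes from 45647078 reads. Barcodes were ranked by UMIs, and the number of cells was set in each library at the minimum of the smoothed second derivative of the cumulative UMI curve between ranks 500 and 60000. This called 4118 barcodes with at least 1166 UMIs in the WT library and 4362 barcodes with at least 1278 UMIs in the Atg5 LEC-KO library. Cells with fewer than 200 genes or with over 25% of UMIs from mitochondrially encoded genes were removed, which left 3906 and 4166 cells. Scrublet, run per library with an expected rate of 6%, called 28 doublets (0.717%) and 29 doublets (0.696%), which were removed.

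The remaining 3878 and 4137 cells were clustered together without batch integration in scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1). Mitochondrial, ribosomal protein, immunoglobulin, T cell receptor variable and sex-linked genes were kept out of the variable genes. Clusters were named from 35 marker lists. LEC-like and blood endothelial cell (BEC)-like cells were each clustered again to name sub-classes. The marker lists were fixed beforehand, whereas the scores and thresholds that turn them into names were set after the clusters had been seen. The marker lists of the Marco-positive medullary and the Ptx3-positive paracortical LECs were merged, because 1 sub-cluster carried both. All class names stand for resemblance to those markers. Sub-clusters led by genes of other cell types were left out as mixed: 12 WT and 4 Atg5 LEC-KO cells among the LECs, and 7 and 1, and 2 and 8, among the BECs. The naming thresholds left a pair of immune clusters unnamed, with 3.58% and 2.29% of the immune cells in the WT library and 6.08% and 2.26% in the Atg5 LEC-KO library. They also left 21.6% and 24.7% of BECs in no sub-class. The LECs analysed comprised 719 and 212 cells, and the BECs 649 and 507 cells.

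With 1 library per genotype there are no replicates, so no test was made and no p-value or standard error is given. Shares of cells carry exact Clopper-Pearson 95% intervals. UMIs were summed over the cells of a class and divided by the class total without mitochondrially encoded genes, and scaled to CPM, the usual unit of relative abundance, with exact Poisson 95% intervals, and ratios of CPM carry exact conditional binomial 95% intervals. All of these intervals cover counting error only and not the variation between animals, pools or preparations. Those of CPM and of ratios take each UMI as independent, so they also leave out the variation between cells and can be too narrow. A count of 0 was set to a floor of 3 counts in a ratio. In the alternatives and in means over niche classes or sub-clusters no ratio was given when both counts were at most 3 or when the floor would turn the direction, a rule set after seeing the data. Ratios are given as Atg5 LEC-KO over WT unless stated otherwise.

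For each of 24 gene lists, the median log2 ratio was taken over members with at least 20 UMIs in the class over both libraries, where at least 5 members met this. The interval of a median was taken from 2000 resamples of the members and describes their spread. Its percentile among 10000 random lists of the same size, matched on mean expression, describes these libraries and is no test. The genes named for a class had at least 50 UMIs over both libraries, a UMI in at least 5% of cells of the library in which they were higher, and a CPM ratio of at least 1.5 in either direction. They were ranked by the bound of the ratio's interval nearest to 1. Up to 15 genes per direction were taken for LECs and up to 5 for each BEC or immune class with at least 100 cells in each library. A gene below 10% of its CPM in another class of the same library was named apart, since RNA from other cells can add to it. Mitochondrial, ribosomal protein, immunoglobulin, T cell receptor variable, haemoglobin, sex-linked and unnamed genes were not eligible. The gene lists, markers, rule for named genes, cell filters and most alternatives were fixed before the data were examined.

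The computation of ratios, intervals and list percentiles was tested on simulated Poisson counts drawn from the summed LEC data. These counts hold no variation between cells, so the test does not cover it. Over 10000 genes, 96.1% of the intervals held the true ratio. Of 100 genes changed 1.5-fold and 100 genes changed 2-fold, 70% and 90% had an interval that left out 1 on the right side. A planted list of 50 genes lay at percentile 100, and 0% of 40 unchanged lists lay outside the central 95% of random lists.

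The alternatives comprised minimums of 500 and 1000 UMIs per cell, at most 10% mitochondrial UMIs, doublet calls kept, Leiden resolutions of 0.5 and 2, uncorrected molecule counts, CPM over all genes, the median gene ratio set to 1, the mean of CPM per cell, other minimums for list members, and an equal-weight mean over LEC niche classes. Thinning each cell to 3000 UMIs was used for the share of cells with an Atg5 UMI. The following were added after seeing the data: a split into male cells (a UMI of a Y-linked gene and none of Xist) and female cells (the reverse), the removal of sub-clusters whose share of a class differed over 10-fold between the libraries, this removal among female BECs, an equal-weight mean over ceiling-like sub-clusters with at least 20 cells in each library, and re-clustering of LECs without their niche markers. A further re-clustering also left out the leading genes of the LEC sub-clusters, the genes named for LECs and the interferon-stimulated, immediate early and NF-kappaB lists. Analyses used python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.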

Results

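Single cells of tumour-draining inguinal lymph nodes were profiled to compare WT mice with mice carrying an Atg5 deletion in lymphatic endothelial cells (LECs), the cells that line lymphatic vessels and the sinuses of the node. Atg5 encodes a protein of the conjugation machinery that builds autophagosomes. There was 1 library per genotype, made from 13 pooled WT nodes and from 9 pooled nodes of Atg5 LEC-KO animals, and hence no replicate check for any difference below. The libraries were close in depth, with 23649554 and 23089918 UMIs over all barcodes, and 3878 and 4137 cells entered the clustering. The median cell held 3502 UMIs and 1527 genes in the WT library and 3348 UMIs and 1469 genes in the other. Both libraries mixed cells of male and female animals in different proportions: among LECs that could be assigned to a sex, 71.3% (95% interval 67.5-74.9) were male in the WT library and 50.9% (43.2-58.5) in the other, and among B cells 79.5% and 50.4%.

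Atg5 transcripts were found at similar levels in the LECs of both libraries. Atg5 (ENSMUSG00000038160.7) lies on the plus strand of chromosome 10 at 44268358-44364291 in mm10. LECs held 40.8 CPM (35.7-46.3, 235 UMIs) in the WT library and 44.1 CPM (34.4-55.7, 70 UMIs) in the library labelled Atg5 LEC-KO, a ratio of 1.08 (0.816-1.42). The ratio was 0.841 (0.528-1.29) in ceiling-like LECs, 0.863 (0.534-1.41) in medullary or paracortical-like LECs, 0.917 (0.688-1.22) in BECs, 0.852 (0.707-1.03) in B cells, 1.52 (1.06-2.23) in CD4 T cells, 1.01 (0.759-1.35) in CD8 T cells and 0.898 (0.600-1.35) in regulatory T cells. That of CD4 T cells changed direction in male cells. An Atg5 UMI was detected in 22.4% of WT LECs and 25% of the others, against 11.8% and 9.94% of B cells, which had median depths of 2688 and 2707 UMIs where LECs had 8192 and 7932. After thinning each cell to 3000 UMIs the shares were 9.24% and 11% of LECs and 13.5% and 9.04% of B cells, which left out 48 and 11 LECs and 866 and 995 B cells as too shallow. The labels do not name the deleted exon, and transcripts counted at their 3' end outside a deleted exon check nothing, so these values neither bear out nor exclude the genotype. The second library is therefore called the KO-labelled library.

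LECs made up a smaller part of the endothelial cells in the KO-labelled library, and the makeup of its LECs differed. LEC-like cells were 52.6% of endothelial cells (49.9-55.2, 719 of 1368) in the WT library and 29.5% (26.2-33.0, 212 of 719) in the KO-labelled library. Floor-like LECs, which resemble the cells under the subcapsular sinus that express Madcam1 and Ccl20, were 19.7% of WT LECs (16.9-22.9, 142 cells) and 3.77% of KO-labelled LECs (1.64-7.30, 8 cells). Medullary or paracortical-like LECs, which resemble the Lyve1-high cells of the inner sinuses, were 8.76% (6.80-11.1, 63 cells) and 42.9% (36.2-49.9, 91 cells). LECs were clustered again without the niche markers, the leading genes of the sub-clusters, the named LEC genes and the interferon, immediate early and NF-kappaB lists. The shares were then 19.7% and 3.77% for floor-like and 6.82% and 39.6% for medullary or paracortical-like LECs. Other genes that differed stayed in, and the niche markers still named the sub-clusters. The LEC share and the floor-like share were also lower in the KO-labelled library within each sex, with LEC shares of 55.3% and 25.9% among male cells and 67.5% and 42.0% among female cells. Cycling LECs were 6.40% and 4.25%. Ceiling-like LECs, which resemble the Ackr4-positive cells of the outer sinus wall, were 65.1% and 49.1%, but this difference of -16.0 percentage points was 0.063 points with doublet calls kept and 4.77 points at Leiden resolution 2, so its direction is not settled. The difference in the LEC share of endothelial cells, -23.1 points, was -36.8 points when cells with over 10% mitochondrial UMIs were left out, and pooling and sorting of the endothelial fraction can set these shares.

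**Figure D1:**
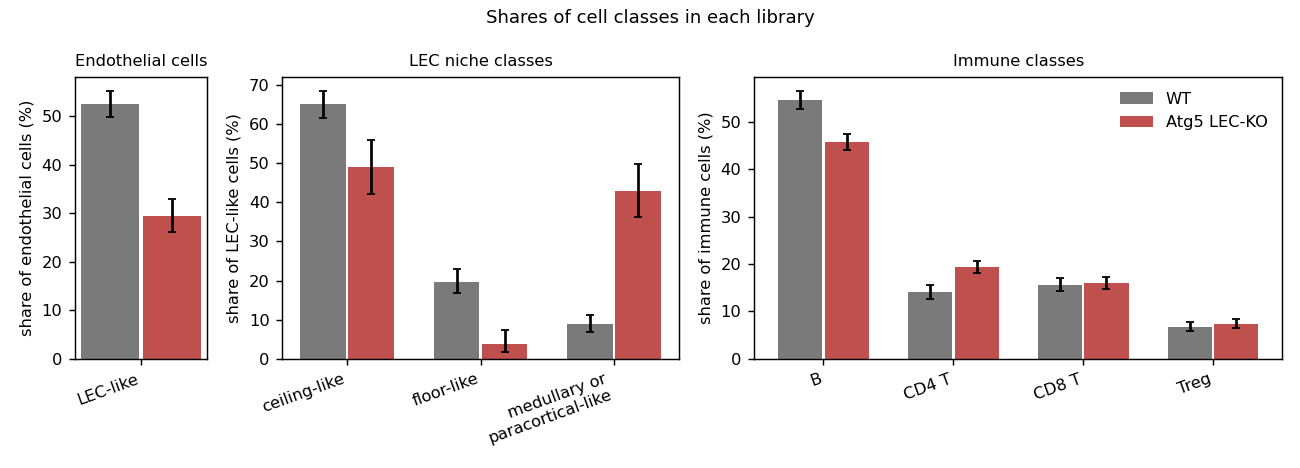
Shares of cell classes in percent for the WT library (grey) and the library labelled Atg5 LEC-KO (red), with bars for shares and lines for exact Clopper-Pearson 95% intervals, which cover counting error only. LEC-like cells are 52.6% and 29.5% of endothelial cells, and medullary or paracortical-like cells are 8.76% and 42.9% of LECs, while CD8 T cells are 15.6% and 16.0% of immune cells.

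Among the BECs, the capillary-like class was the largest, with 51.6% (47.7-55.5) of WT and 55.2% (50.8-59.6) of KO-labelled BECs. High endothelial venule-like cells, through which lymphocytes enter the node, were 10.2% (7.95-12.8) and 7.69% (5.53-10.4), and arterial-like cells 4.93% and 4.73%. Venous-like cells were 5.86% (4.18-7.95) and 2.17% (1.09-3.85), and cycling BECs 5.86% and 5.52%.

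In LECs, interferon-stimulated genes were higher and immediate early and inflammatory genes lower in the KO-labelled library. Of the 47 measured interferon-stimulated genes, 42 were higher and 5 lower, with a median log2 ratio of 0.75 (0.61 to 0.90) at percentile 100 of random lists. Among them, Rsad2, which encodes the antiviral protein viperin, was 16.6-fold higher (13.0-21.4), Ifit3 7.01-fold, Ifit2 3.65-fold (3.08-4.31) and Gbp7, a guanylate-binding protein, 1.80-fold (1.65-1.98), whereas Ifitm3, the most abundant member, had a ratio of 0.980 (0.941-1.02). All 31 dissociation and immediate early genes were lower, with a median of -1.09 (-1.32 to -0.83) at percentile 0: the ratio was 0.429 (0.411-0.447) for Fos, 0.529 (0.507-0.552) for Jun, 0.325 (0.306-0.344) for Zfp36 and 0.298 (0.275-0.323) for Fosb. NF-kappaB and inflammatory genes had 4 members higher and 28 lower and a median of -0.54 (-1.04 to -0.28), with ratios of 0.571 (0.524-0.620) for Nfkbia, 0.522 (0.476-0.571) for Csf1, which is also on the marker list of floor-like LECs, and 0.204 (0.149-0.273) for the chemokine Cxcl1. The largest shift of the median over all genes in any class was 0.043, far below these medians. The mitochondrial share of UMIs, a measure of cell quality, also differed in LECs, at 7.24% in the WT and 10.4% in the KO-labelled library, and in ceiling-like LECs, at 7.5% and 11.5%, while it was 10.02% and 10.13% in BECs and 9.56% and 9.56% in B cells. With at most 10% mitochondrial UMIs per cell the medians were 0.70 for interferon-stimulated in LECs and -0.85 for dissociation and immediate early in LECs. Averaged over ceiling-like and medullary or paracortical-like LECs with equal weights, which takes out a shift between these classes and leaves out floor-like and cycling cells, the medians were 0.61 for interferon-stimulated, -0.49 for immediate early and -0.12 for NF-kappaB genes.

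The medians of these lists were also taken within both niche classes with enough cells. Medullary or paracortical-like LECs had 41 interferon-stimulated genes higher and 4 lower, with a median of 1.1 (0.74 to 1.37). In these cells Rsad2 had 4 UMIs in the WT library and 362 in the KO-labelled library, a ratio of 61.4 (23.8-226), and was detected in 3.17% and 27.5% of cells. The chemokine gene Cxcl10 (chromosome 5, 92346638-92348889) was 19.0-fold higher (12.2-31.3), Ifit2 9.34-fold (5.79-16.0) and Ifit1 8.26-fold (5.29-13.6) in the same cells. Ceiling-like LECs had an interferon median of 0.16 (0.02 to 0.42), with 29 members higher and 16 lower, and Cxcl10 had 153 and 3 UMIs there, a ratio of 0.106 (0.0215-0.314). The ceiling median was -0.23 in female cells and -0.06 without the sub-clusters found almost wholly in the WT library. All 31 immediate early genes were lower in ceiling-like LECs, with a median of -0.97 (-1.13 to -0.76), while 15 were higher and 15 lower in medullary or paracortical-like LECs, with a median of 0.03 (-0.10 to 0.23). Ceiling-like LECs are made of different sub-clusters in the libraries: 107 of 468 WT and 9 of 104 KO-labelled cells lay in a sub-cluster led by immediate early genes such as Atf3 and Egr1, and 87 and 1 in another. Averaged over the 3 ceiling-like sub-clusters with enough cells in each library, the immediate early median was -0.64 (-0.74 to -0.51). NF-kappaB genes had a median of -0.31 (-0.61 to -0.22) in ceiling-like LECs, where the mean over the same sub-clusters gave -0.24 (-0.41 to 0.03), and of -0.07 (-0.21 to 0.04) in medullary or paracortical-like LECs. Whether the classes differ in these medians was not tested.

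Other gene lists in LECs had medians from -0.61 to 0.24. Core autophagy genes had 14 members higher and 15 lower, with a median of -0.02 (-0.15 to 0.10) at percentile 19.8: the ratio was 0.908 (0.835-0.986) for Gabarap, 1.06 (0.955-1.17) for Map1lc3b and 1.57 (1.32-1.86) for Wipi1. The core autophagy median was 0.05 (-0.17 to 0.22) in medullary or paracortical-like LECs and -0.10 (-0.24 to 0.05) in ceiling-like LECs, where the mean over sub-clusters gave -0.21 (-0.34 to -0.15), with 6 members higher and 23 lower. Autophagy receptors had a median of -0.08 (-0.22 to 0.01), with Sqstm1, which encodes the receptor p62, at 0.858 (0.776-0.948). Lysosomal genes had 22 members higher and 8 lower and a median of 0.24 (0.11 to 0.39) at percentile 99.8, among them Lamp2 at 1.33 (1.24-1.43), but the median was 0.04 averaged over niche classes and 0.07 in male cells. Extracellular matrix and TGF-beta genes had a median of 0.18 (-0.02 to 0.42), with the basement membrane collagen gene Col4a1 at 2.05 (1.97-2.14) and Fn1, fibronectin, at 2.58 (2.46-2.70), and Ccn1 at 0.407 (0.387-0.429). Chemokines and scavenging receptors had 9 members higher and 13 lower and a median of -0.61 (-1.26 to 0.31), with ratios of 0.331 (0.309-0.355) for Ackr4 and 0.313 (0.273-0.357) for Ackr3, a pair of chemokine scavengers. Ackr4 marks ceiling-like LECs and is among the leading genes of a ceiling-like sub-cluster, so its ratio can carry a difference in makeup. The median of this list was -0.40 in ceiling-like and -0.24 in medullary or paracortical-like LECs. In the mean over ceiling-like sub-clusters it was -0.02, with 7 members higher and 7 lower. LEC identity genes had a median of 0.05 (-0.24 to 0.93), with the transcription factor gene Prox1 at 1.01 (0.962-1.06), Lyve1 at 3.22 (3.12-3.33), Klf2 at 0.399 (0.368-0.432) and Klf4 at 0.50 (0.471-0.532). Lyve1 is on the marker list of medullary or paracortical-like LECs, which were 8.76% of WT and 42.9% of KO-labelled LECs. Its ratio can therefore carry this difference in makeup. Cell cycle genes had 5 members higher and 18 lower and a median of -0.23 (-0.57 to -0.04), which was 0.43 averaged over niche classes. That mean leaves out the cycling LECs, 46 WT and 9 KO-labelled cells, by construction. Nuclear oxidative phosphorylation genes had a median of 0.11 (0.00 to 0.22), but -0.08 in ceiling-like and 0.02 in medullary or paracortical-like LECs. In LECs as a whole, fatty acid oxidation and lipid droplet genes had a median of 0.08 (-0.13 to 0.19), NRF2 targets 0.06 (-0.10 to 0.26) and T cell costimulatory and inhibitory ligands 0.03 (-0.36 to 0.39). Sphingosine-1-phosphate pathway genes had a median of 0.01 (-0.15 to 0.07), adhesion and junction genes 0.01 (-0.15 to 0.20), unfolded protein response genes -0.02 (-0.23 to 0.16), MHC class I genes -0.02 (-0.18 to 0.12) and MHC class II genes -0.19 (-0.68 to 0.64).

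Single genes in LECs that were highest in the KO-labelled library included interferon-inducible genes and imprinted growth-related genes. Ifi211 (chromosome 1, 173896345-173913046) was 23.6-fold higher (13.4-44.9) and Ifi204, on the same chromosome at 173747293-173766943, 12.6-fold (8.98-18.1). Cmpk2 (chromosome 12, 26469204-26479837), which lies beside Rsad2 (26442746-26456452), was 5.19-fold higher (4.28-6.30), and Ifit3b 6.93-fold. The imprinted genes H19, Mest and Igf2 were 12.9-fold (11.3-14.8), 8.63-fold (6.99-10.7) and 7.19-fold (6.06-8.56) higher. H19, a non-coding RNA gene, and Igf2, a growth factor gene, lie on chromosome 7 at 142575529-142578143 and 142650766-142666816. The others were Rerg at 19.4-fold (9.40-44.9), Mfap3l at 6.51, the mechanosensitive channel gene Piezo2 at 5.0, the mannose receptor gene Mrc1 at 4.79, the sodium channel gene Scn3a at 4.57 and Angpt2, a ligand of the Tie2 receptor, at 4.36-fold (3.95-4.81). All 15 were also higher in male cells, in female cells and in the mean over niche classes, with log2 values from 1.01 for Scn3a to 3.64 for Rsad2 in that mean. H19, Ifi211, Ifi204, Mrc1, Mest and Igf2 are also among the leading genes of the medullary or paracortical-like sub-cluster, and Mrc1 is one of its markers. Slc38a1, Sp100, Pde3b, Ccnd2 and Gpihbp1 were 5.68-, 3.75-, 4.11-, 3.34- and 3.10-fold higher at levels that RNA from other cells can reach, and the last pair had log2 ratios of -0.92 and -1.17 in male cells. In the mean over niche classes the log2 ratios of Slc38a1, Sp100, Pde3b, Ccnd2 and Gpihbp1 were 1.65, 0.926, 0.848, 0.703 and 1.63.

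Among the genes that were lowest in KO-labelled LECs, several encode immediate early factors and others lead the floor-like clusters. The immediate early genes Nr4a1, Atf3 and Egr3 had ratios of 0.190 (0.160-0.224), 0.196 (0.165-0.231) and 0.181 (0.130-0.246). Ptn, which encodes the growth factor pleiotrophin, was at 0.0894 (0.0383-0.178), the potassium channel gene Kcnj2 at 0.113 (0.0629-0.189), the prostaglandin receptor gene Ptger4 at 0.178 (0.112-0.271) and Crip1 at 0.186 (0.126-0.265). The muscarinic receptor gene Chrm2 had 123 and 2 UMIs, a ratio of 0.059 (0.00707-0.218). In the mean over niche classes these 8 genes had log2 ratios from -2.82 for Ptn to -0.92 for Ptger4. The others were Rgs4 at 0.101 (0.0629-0.154), Il4i1 at 0.0805 (0.0366-0.154), the metallothionein gene Mt2 at 0.121 (0.0811-0.174), Bmp2 at 0.179 (0.149-0.212), the desmosomal gene Dsg2 at 0.221 (0.181-0.269), the gelatinase gene Mmp9 at 0.128 (0.0768-0.203) and Nkx6-1, with 131 UMIs and 1 UMI, at 0.0277 (0.000697-0.157). The mean over niche classes, which leaves out floor-like cells and with them most UMIs of several of these 7 genes, had log2 ratios nearer 0 for the first 5, at -0.41, -0.38, -0.000593, -0.57 and -0.06. Mmp9 had 1.44 in that mean on too few UMIs to give a direction, and Nkx6-1 had too few for a ratio. Rgs4, Mt2, Bmp2, Mmp9 and Nkx6-1 are also among the leading genes of the floor-like clusters, and Atf3 and Egr3 among those of a ceiling-like one. Col15a1, Fcgr2b, Nfkbid, Cd226 and Cecr2 were lower at levels that RNA from other cells can reach, with ratios of 0.182, 0.0893, 0.055, 0.197 and 0.140. Col15a1 is also among the leading genes of a floor-like sub-cluster that held 120 WT and 8 KO-labelled cells. In the mean over niche classes Col15a1 had a log2 ratio of 2.5 on few UMIs, while Fcgr2b and Cd226 had too few for a ratio. The intervals of Nfkbid, with 66 UMIs and 1 UMI, and Cecr2, with 52 and 2, were 0.00137-0.317 and 0.0165-0.531.

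**Figure D2:**
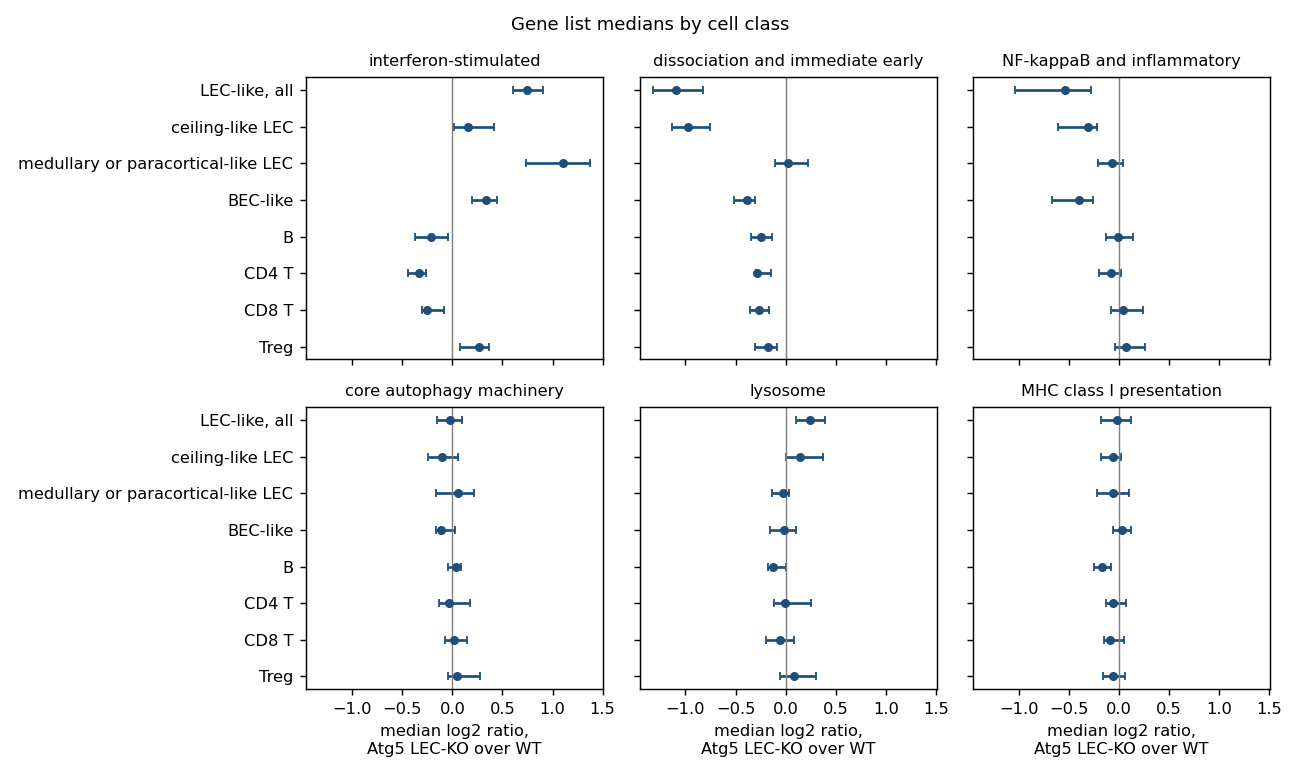
Median log2 ratio of the library labelled Atg5 LEC-KO over the WT library for 6 gene lists (panels) in 8 cell classes, with points for medians and lines for 95% intervals from resampling the list's members. The interferon-stimulated median is 0.75 in LECs and 1.1 in medullary or paracortical-like LECs, while the core autophagy median is -0.02 in LECs.

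BECs, in which Atg5 was not targeted by the design, also had higher interferon-stimulated and MHC class II genes in the KO-labelled library. The interferon-inducible chemokine gene Cxcl9 (chromosome 5, 92321347-92328079) had 295 CPM (276-315) in the WT library and 2295 CPM (2238-2353) in the other, a ratio of 7.77 (7.25-8.35). Serping1, which encodes the C1 inhibitor, was 8.71-fold higher (6.11-12.8), Cxcl10 5.84-fold (5.05-6.79), Gbp10 10.4-fold (4.14-33.5) and Gbp2 3.43-fold (3.12-3.78). Of 47 interferon-stimulated genes 41 were higher, with a median of 0.34 (0.20 to 0.44), and of 11 MHC class II genes 9 were higher, with a median of 1.1 (0.32 to 1.58), although the MHC class II genes that pass the rule for naming lie at levels that RNA from other cells can reach. A sub-cluster led by the same genes held 62 of 507 KO-labelled BECs (12.2%) and 2 of 649 WT BECs (0.308%), and may be a feature of that pool and not a cell type. Without it the medians were -0.29 and -0.19, and Cxcl9, Cxcl10, Gbp10 and Gbp2 changed sign. Since the same genes define the sub-cluster, leaving it out lowers these values by construction. In female cells, of which 1 lay in that sub-cluster, the medians were 0.39 and 2.70, and 0.37 and 2.72 without that cell, but Gbp2 had a log2 ratio of -0.19, Serping1 had 7 WT UMIs and 0 in the KO-labelled library, and Gbp10 had none. The MHC class II median of 2.72 rests on only 5 members (0.46 to 3.32). In CD8 T cells 7 of 9 MHC class II members were also higher, with a median of 0.95 (0.14 to 1.54). Cd74 and H2-Ob lay there at levels that RNA from other cells can reach, and Cd74 changed sign in male cells. The MHC class II median was 0.13 in CD4 T cells, 0.30 in regulatory T cells, 0.00 in B cells and -0.19 in LECs.

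Immediate early and NF-kappaB genes were lower in BECs of the KO-labelled library, with 28 of 31 and 24 of 27 members lower and medians of -0.39 (-0.51 to -0.31) and -0.40 (-0.67 to -0.26). Jun had a ratio of 0.704 (0.674-0.736), Zfp36 0.643 (0.614-0.673), Nfkbia 0.712 (0.668-0.758) and Cxcl1 0.432 (0.370-0.505). The immediate early median was -0.69 (-0.81 to -0.54) in the capillary-like class, but changed sign there in female cells. Cell cycle genes had a median of -0.27 (-0.65 to -0.07) in BECs as a whole, but 0.61 (0.20 to 1.32) in the capillary-like class, with 13 of 14 members higher. That class leaves out the cycling BECs, 38 WT and 28 KO-labelled cells. Unfolded protein response genes had a median of 0.15 (0.03 to 0.17) in BECs as a whole. In female BECs the medians were -0.12 for immediate early, 0.12 for NF-kappaB, 0.10 for cell cycle and -0.01 for unfolded protein response genes. The lowest genes were Arc, an immediate early gene, at 0.0723 (0.0229-0.176), Itm2a at 0.147 (0.0971-0.216), Crip1 at 0.245 (0.206-0.290), Pcp4l1 at 0.205 (0.121-0.332) and the urea transporter gene Slc14a1 at 0.280 (0.211-0.368). Itm2a and Pcp4l1 are also the leading genes of a capillary-like sub-cluster that held 76 of 649 WT and 19 of 507 KO-labelled BECs. At levels that RNA from other cells can reach, Ciita, the regulator of MHC class II genes, was 5.97-fold, H2-Ab1 2.98-fold, Cd74 2.61-fold, H2-DMa 3.32-fold and H2-Eb1 2.15-fold higher, and Egr3, Cd24a, Rgs16, Nfkbid and Dock10 had ratios of 0.361, 0.445, 0.475, 0.474 and 0.496. The directions of Cd24a and, on few UMIs, of Pcp4l1 turned in female BECs.

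Within the capillary-like class alone, Cxcl10 was 20.1-fold higher (15.1-27.4), Serping1 25.8-fold (13.4-57.1), Cxcl9 11.5-fold (10.5-12.6) and Ubd, which encodes a ubiquitin-like modifier, 7.22-fold (6.24-8.39). Ido1, which encodes a tryptophan-degrading enzyme, had 2 and 94 UMIs, a ratio of 44.0 (11.9-369). Pcp4l1, Itm2a, Arc, Abca2 and Cd24a were at 0.0578, 0.111, 0.0808, 0.0781 and 0.141. At levels that RNA from other cells can reach, Cenpe, Cd74, H2-Ab1, H2-Eb1 and H2-Aa were 8.43-, 3.98-, 4.18-, 2.72- and 1.99-fold higher, and Egr3, Nfkbid, Stk17b, Tnc and Scd1 were at 0.296, 0.406, 0.463, 0.474 and 0.405. Sub-clusters in different proportions make up this class, 1 of them with 8.47% of WT and 17.2% of KO-labelled BECs and the interferon-led one with 0.308% and 12.2%. The one led by Itm2a and Pcp4l1, with Cd24a among its leading genes, held 76 and 19 cells. The lower values of these 3 genes and its smaller share are therefore not separate observations. Cxcl9 is on the marker list that names this class, and is the only such marker among the leading genes of the interferon-led sub-cluster. That sub-cluster joined the class at a score of 0.4, where over 0.3 was needed. The class was thus drawn in part by a gene given here as higher. With at most 10% mitochondrial UMIs, where the class was drawn anew, the log2 ratios were -1.57 for Cxcl10 in capillary BECs, -0.66 for Serping1 in capillary BECs, and, in the same cells, -0.14 for Cxcl9 and -0.78 for Ubd. Serping1 had 4 and 2 UMIs there, and Ido1 too few for a ratio. Cd74, H2-Ab1, H2-Eb1 and H2-Aa changed sign under that limit too. Without the interferon-led sub-cluster, Cxcl10, Cd74 and H2-Aa changed sign as well.

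Among immune cells, B cells made up a smaller and CD4 T cells a larger part in the KO-labelled library. B cells were 54.7% of immune cells (52.7-56.6, 1361 of 2489) in the WT library and 45.8% (44.1-47.5, 1559 of 3405) in the KO-labelled library. CD4 T cells were 14.1% (12.7-15.5) and 19.4% (18.1-20.7), CD8 T cells 15.6% (14.2-17.1) and 16.0% (14.8-17.3), and regulatory T cells 6.75% (5.79-7.81) and 7.43% (6.57-8.36). Plasma cells were 0.362% and 0.411%, cycling cells 2.09% and 2.09%, neutrophils 0.241% and 0.147% and migratory dendritic cells 0.321% and 0.411%. The difference in CD4 T cells, 5.32 percentage points, was 3.08 points with at most 10% mitochondrial UMIs and -1.21 points in female cells. That in the B cell share of immune cells, -8.89 points, was -5.23 points at Leiden resolution 2 and -3.87 points in female cells.

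Interferon-stimulated genes were lower in B, CD4 T and CD8 T cells of the KO-labelled library and higher in regulatory T cells. The medians were -0.21 (-0.37 to -0.04) in B cells, -0.34 (-0.44 to -0.26) in CD4 T cells, -0.25 (-0.30 to -0.08) in CD8 T cells and 0.27 (0.08 to 0.37) in regulatory T cells, with 14 of 46, 9 of 44, 15 of 46 and 30 of 42 members higher. The makeup of the B cells differed too. A cluster with interferon-stimulated genes such as Ifit3 among its leading genes held 3.16% of WT and 1.41% of KO-labelled B cells. A cluster with Egr2 and Egr3 among its leading genes held 25.3% and 16.2%. Such genes help to group the cells, so these shares and the B cell medians are not separate observations. Medians without these clusters were not taken. Ifit3 had ratios of 0.508 (0.381-0.676) in B cells and 0.415 (0.279-0.614) in CD4 T cells, and Ifit1 was 3.19-fold higher (1.70-6.50) in regulatory T cells. Immediate early genes were lower in all 4 classes, with medians of -0.25 in B, -0.28 in CD4 T, -0.27 in CD8 T and -0.18 in regulatory T cells. T cell egress and homing genes had medians of 0.01, 0.00 and 0.11 in CD4, CD8 and regulatory T cells, naive and memory genes 0.09, 0.00 and 0.12, activation and exhaustion genes -0.07, -0.23 and -0.03, and cytotoxic effector genes -0.13, 0.08 and 0.00. In CD8 T cells 18 of 20 activation and exhaustion genes were lower, among them Egr1 at 0.807 (0.696-0.938) and Tox at 0.828 (0.696-0.986). B cell activation genes had a median of -0.08 (-0.18 to 0.00), with the homing-related transcription factor gene Klf2 at 0.696 (0.670-0.723). The interferon median of CD4 T cells was 0.03 with a minimum of 500 UMIs, and in male cells the immediate early medians were 0.18 in CD4 T and 0.12 in CD8 T cells and the log2 ratio of Ifit1 in regulatory T cells was -0.33.

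The largest single differences in immune classes were modest beside those of LECs. Cpt1a (chromosome 19, 3322334-3385733), the entry enzyme of mitochondrial fatty acid oxidation, was 1.97-fold higher (1.72-2.26) in B cells, followed by Fancl, Slc37a2, Dera and Snx14 at 1.87-, 1.97-, 1.80- and 1.83-fold. Neb, Klhl21, Galnt11, Acaca and Larp1b were 3.46-, 4.15-, 3.15-, 3.19- and 2.72-fold higher in CD4 T cells, and the log2 ratio of Neb was -0.04 in male cells. Snx19, Rmdn1, Mid1, Flvcr1 and Haus6 were 3.95-, 4.05-, 3.49-, 2.5- and 2.38-fold higher in CD8 T cells, and Abhd13, Nck2, Immp2l and Dym 5.99-, 4.70-, 3.44- and 3.50-fold higher in regulatory T cells. Genes named as lower in more than 1 class are given below, and the other lower genes were not compared across classes. Hist1h2bc was lower in B cells at 0.423 (0.343-0.519) and Uqcc3 in CD4 T cells at 0.317 (0.190-0.521). Hivep3, Edf1, Slc10a3 and Ormdl3 were lower in CD8 T cells at 0.288, 0.386, 0.302 and 0.295. Kcna2 and Mrps17 were lower in regulatory T cells at 0.310 and 0.333. At levels that RNA from other cells can reach, the higher genes included Spns2 at 1.70-fold and Hip1 at 1.58-fold in B cells, Cd8b1, Il2rb and Akap12 at 2.03-, 1.80- and 1.61-fold in CD4 T cells, Cd74, H2-Ob and Akap12 at 1.93-, 1.61- and 1.71-fold in CD8 T cells, and Egr3, Ly6c1 and Top2a at 2.95-, 1.83- and 1.67-fold in regulatory T cells. The lower ones included Rgs1 at 0.592 in B cells, Plk2 and Arhgap29 at 0.555 and 0.664 in CD4 T cells, Hspb1, Rab11a, Nxn and Tcf4 at 0.431, 0.577, 0.489 and 0.560 in CD8 T cells, and Cd81 at 0.446 in regulatory T cells. The directions of Cd8b1, Il2rb, Plk2, Cd74, Hspb1 and Ly6c1 turned in male cells, in female cells or with a minimum of 500 UMIs.

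The genes named as lower in more than 1 class were lower in the KO-labelled library in LECs, BECs and all 4 immune classes alike. They follow from the naming rule and are no count of all such genes. Tmsb10 (chromosome 6, 72957347-72958748), which encodes an actin-sequestering thymosin, had ratios of 0.599 in LECs, 0.603 in BECs, 0.434 in B cells, 0.508 in CD4 T cells, 0.454 in CD8 T cells and 0.455 in regulatory T cells. Snrpd2 (chromosome 7, 19149722-19153542), a core gene of the splicing machinery, ranged from 0.253 in B cells to 0.429 in BECs. Ppp1ca, a phosphatase gene, ranged from 0.425 in B cells to 0.607 in regulatory T cells, Ube2m from 0.288 in CD4 T cells to 0.475 in BECs, Nab2 from 0.197 in LECs to 0.474 in CD8 T cells and Crip1 from 0.186 in LECs to 0.638 in CD8 T cells.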

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

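The tests on the patterns below were chosen after their results had been seen, apart from the splits of LECs by sex for interferon-stimulated and for immediate early genes and the mean over ceiling-like sub-clusters, which were set out before their results were known. The interferon differences between LECs or BECs and the lymphocyte classes are part of the first pattern.

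Interferon-stimulated genes were higher in the LECs and BECs of the KO-labelled library. A shift between ceiling-like and medullary or paracortical-like LECs as the whole cause is argued against by the mean over these classes. That log2 median of 0.611 is built from 1.1 in medullary or paracortical-like and 0.16 in ceiling-like LECs. The medullary or paracortical-like class merges the markers of both niches and is 1 sub-cluster with Ifi211 and Ifi204 among its leading genes. A shift within either class is not taken out by this mean and stays open. Cells of 1 sex only are argued against by the lower of the male and female medians, 0.505 in LECs and 0.376 in BECs. These splits do not take out makeup. Medullary or paracortical-like cells were 9.41% of female LECs in the WT library and 55.8% in the KO-labelled library, and the ceiling-like median changed sign in female cells. Among male BECs, 44 KO-labelled cells and 1 WT cell lay in the interferon-led sub-cluster. A rise in every class of the library is argued against by the medians of B, CD4 T and CD8 T cells, the highest of which was -0.208. However, the median was 0.27 in regulatory T cells and 0.0275 for interferon-stimulated in CD4 T cells with a minimum of 500 UMIs. Whether 1 sub-cluster carries the pattern in BECs as a whole stays open, since the median of -0.292 without it is lowered by leaving out cells grouped by these very genes, while female BECs, of which 1 lay in it, had a median of 0.39 but a log2 ratio of -0.19 for Gbp2 in BECs and too few UMIs of Serping1 and Gbp10 to judge them. With 1 library per genotype, the genotype cannot be told apart from another difference between the pools, such as the state of single animals or their tumours, and both stay open.

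Immediate early genes were lower in the KO-labelled library, with medians of -1.09 in LECs as a whole, -0.39 in BECs and -0.69 in capillary-like BECs. The LEC difference was smaller in the mean over niche classes. A shift in LEC niche classes as the whole cause is argued against by the median of -0.973 within ceiling-like LECs, where a shift between sub-clusters as the whole cause is argued against in turn by the mean over 3 of them, -0.64, although the median was 0.03 in medullary or paracortical-like LECs. Cells of 1 sex only are argued against in LECs by the higher of the male and female medians, -0.715. In BECs, CD4 T and CD8 T cells this stays open. The immediate early median was smaller in female BECs and changed sign in female capillary-like BECs and in male CD4 T and CD8 T cells. A fold shared by all classes is argued against by the median in LECs minus that of the lowest immune class, -0.81. Tissue digestion raises these genes, and with 1 library per genotype a difference in handling between the pools that acts more on LECs, whose mitochondrial share also differed at 7.24% and 10.4%, could produce the pattern and cannot be told apart from the genotype.

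LECs were a smaller part of the endothelial cells in the KO-labelled library, and floor-like cells a smaller part of its LECs. The cell threshold as the cause is argued against by the difference in LEC share at shared minimums of 500 and 1000 UMIs, the smaller of which was -22.4 percentage points. Cells of 1 sex only are argued against by the smaller of the male and female differences, -25.5 points for the LEC share and -13.5 points for the floor-like share. With 1 library per genotype, yields of digestion and sorting that differ between the pools could set both shares and cannot be told apart from the genotype.

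The remaining differences were singled out because the medians of a gene list, with their intervals over members, lay on opposite sides of 0 in an endothelial and an immune class, and none of these differences was tested. For interferon-stimulated genes, the median log2 ratio in LECs minus that in B, CD4 T and CD8 T cells was 0.954, 1.08 and 0.994, and that in BECs minus the same classes was 0.549, 0.677 and 0.589. For lysosomal genes, LECs minus B cells gave 0.368, although the median of lysosome in LECs was 0.04 in the mean over niche classes and 0.07 in male cells. For nuclear oxidative phosphorylation genes, LECs minus B cells gave 0.209, although the medians were -0.08 in ceiling-like and 0.02 in medullary or paracortical-like LECs. For cell cycle genes, LECs minus B cells and minus regulatory T cells gave -0.416 and -0.615, although the LEC median was 0.43 in the mean over niche classes and that of cell cycle in Treg cells -0.0144 with a minimum of 500 UMIs, and BECs minus the same classes gave -0.448 and -0.647, although the capillary-like BECs had a median of 0.61. The values of 0.43 and 0.61 leave out the cycling endothelial cells.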

How the results depend on the processing

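The splits by sex, the removal of sub-clusters found almost wholly in 1 library, the mean over ceiling-like sub-clusters and the re-clusterings of LECs were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library. The splits by sex left few cells in some classes, with 42 WT CD4 T cells and 24 WT regulatory T cells female, and genes with a few UMIs moved freely there. No ratio was taken where both counts were at most 3 or where the floor for a count of 0 alone would set the direction, a rule chosen after seeing the data. A value within the main 95% interval was counted as unmoved. A sign was counted as changed, here and below, only where the main interval left out 0. Other changes of sign were counted as unmoved or moved. For the shares and the leading list medians, 148 of the values under alternatives planned beforehand were unmoved, 9 moved and 2 changed sign, and under added alternatives 37, 16 and 4. For single genes and other lists the numbers were 2698, 179 and 21 under planned and 512, 212 and 41 under added alternatives. Uncorrected molecule counts, CPM over all genes, the median gene ratio set to 1 and other minimums for list members moved none of the leading medians. The shares do not use these settings and were not recomputed under them. Below, differences in shares are in percentage points and other values are log2 ratios, KO-labelled over WT. The cause was not tested, except where the alternative leaves out the cells or classes that carry a difference.

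With a minimum of 500 UMIs the sign changed for Abca2 in capillary BECs (1.28, on 1 and 4 UMIs), for Cd8b1 (-0.514), Plk2 (0.382), Il2rb in CD4 T cells (-0.0156), the median of interferon-stimulated in CD4 T cells (0.0275) and that of cell cycle in Treg cells (-0.0144, and -0.0229 with doublet calls kept). The ceiling LEC share of LECs differed by -3.38 with a minimum of 1000 UMIs, 0.063 with doublet calls kept, 4.77 at Leiden resolution 2 and -3.22 with niche markers left out of the re-clustering. The medullary or paracortical-like share differed by 26.0 with doublet calls kept, and the B cell share of immune cells by -5.23 at resolution 2. With at most 10% mitochondrial UMIs the LEC share of endothelial cells differed by -36.8 and the CD4 T share by 3.08. In capillary BECs, drawn anew under that limit, the sign changed for Cxcl10 (-1.57), Serping1 (-0.66, on 4 and 2 UMIs), Cxcl9 (-0.138), Ubd (-0.776), Cd74 (-2.0), H2-Ab1 (-1.0), H2-Eb1 (-1.36), H2-Aa (-1.75), Tnc (0.064), MHC class I genes (-0.543) and interferon-stimulated genes (-0.521). With the mean of CPM per cell the immediate early median in BECs was -0.293.

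In the mean over LEC niche classes, which leaves out floor-like and cycling cells by construction, the sign changed for Mmp9 (1.44), Col15a1 (2.5) and cell cycle genes (0.427), but Mmp9 and Col15a1 keep few UMIs in these classes, and those of Mmp9 are too few to give a direction. The medians of lysosome in LECs (0.0419), NF-kappaB (-0.118) and dissociation and immediate early in LECs (-0.489) moved towards 0.

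In male cells the LEC share of endothelial cells differed by -29.4, that of medullary or paracortical-like LECs by 23.3 and that of regulatory T cells by 2.76, and the medians were 0.0717 for lysosome in LECs and -0.715 for immediate early genes in LECs. The sign changed in male cells for Ccnd2 (-0.921) and Gpihbp1 (-1.17) in LECs, fatty acid oxidation and lipid droplets in B cells (-0.0083), Neb (-0.041), Atg5 (-0.069) and immediate early genes (0.182) in CD4 T cells, Cd74 (-1.21), Hspb1 (1.05) and immediate early genes (0.115) in CD8 T cells, and Ifit1 in regulatory T cells (-0.327).

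In female cells the differences in shares were -24.0 for the ceiling LEC share of LECs, 46.4 for medullary or paracortical-like LECs, -3.87 for the B cell share of immune cells, -1.17 for regulatory T cells, and, with a changed sign, -1.21 for CD4 T cells and -0.789 for all T cells. The medians were 0.505 for interferon-stimulated and -1.61 for immediate early genes in LECs, and 2.70 for MHC class II and -0.121 for immediate early genes in BECs. The sign changed in female cells for interferon-stimulated genes in ceiling-like LECs (-0.233), and in BECs for Serping1 (-1.78, a bound from 7 and 0 UMIs), Gbp2 (-0.188), Pcp4l1 (0.442, on 3 and 6), Cd24a (1.12), NF-kappaB (0.12), unfolded protein response (-0.011) and cell cycle genes (0.10). It also changed in capillary BECs for Cd24a in capillary BECs (0.0196, on 4 and 8 UMIs), Nfkbid (2.48, on 1 and 11), NF-kappaB (0.468) and immediate early genes (0.179), and for Plk2 (0.796, on 1 and 6) in CD4 T and Ly6c1 (-1.26) in regulatory T cells.

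Without sub-clusters found almost wholly in 1 library, which takes out the interferon-led BECs by construction, interferon-stimulated and MHC class II genes in BECs had medians of -0.292 and -0.194. The sign also changed for Cxcl9 (-0.228), Cxcl10 (-0.987), Gbp10 (-0.34), Gbp2 in BECs (-0.527), Ciita in BECs (-0.411), H2-Ab1 in BECs (-0.0602), Cd74 (-0.369) and H2-Eb1 (-0.194) in BECs, for interferon-stimulated in ceiling LECs (-0.0592), and in capillary BECs for Cxcl10 (-1.63), Cd74 in capillary BECs (-0.225), H2-Aa (-0.682), MHC class I (-0.25), MHC class II (-0.105) and interferon-stimulated genes (-0.327). In female BECs without the same sub-clusters the medians were 2.72 for MHC class II, on 5 members, and -0.115 for dissociation and immediate early in BECs, and the sign changed for NF-kappaB and inflammatory in BECs (0.136) and cell cycle in BECs (0.115).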

Other observations

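The splits by sex behind some values here were chosen after the data had been seen, and no test was run on them. In B cells of the KO-labelled library 17 of 21 MHC class I genes were lower, with a median log2 ratio of -0.18 (-0.25 to -0.08), among them Psmb10, an immunoproteasome subunit gene, at 0.640 (0.522-0.783) and H2-K1 at 0.854 (0.826-0.882), while B2m had a ratio of 1.04 (1.01-1.06). Nuclear oxidative phosphorylation genes had 21 of 31 members lower in B cells, with a median of -0.10 (-0.15 to -0.04), and fatty acid oxidation and lipid droplet genes 20 of 29 higher, with a median of 0.12 (0.02 to 0.18). The latter median changed sign in male cells. Regulatory T cells had 9 of 11 cell cycle genes higher, with a median of 0.38 (0.25 to 0.74), among them Top2a at 1.67 (1.08-2.66), a level that RNA from other cells can reach, although the median of cell cycle in Treg cells was -0.0144 with a minimum of 500 UMIs.

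In ceiling-like LECs, extracellular matrix and TGF-beta genes had 21 of 30 members higher and a median of 0.27 (0.11 to 0.42), and LEC identity genes 15 of 23 higher and a median of 0.23 (-0.04 to 0.55). In the mean over ceiling-like sub-clusters, chosen after seeing the data, these medians were 0.10 (-0.07 to 0.34) and 0.01 (-0.26 to 0.27). In medullary or paracortical-like LECs, LEC identity genes had 17 of 24 members lower and a median of -0.21 (-0.44 to -0.06).

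Several endothelial sub-clusters held cells of nearly 1 sex. A capillary-like sub-cluster with Abcc9, Celf4, Esm1 and Angpt2 among its leading genes was 100% male (91.4-100) in the WT library, with 41 male and 0 female cells, and 97.0% male (89.6-99.6) in the KO-labelled library, with 65 male and 2 female cells, although female BECs were present in both libraries. The interferon-led BEC sub-cluster of the KO-labelled library held 44 male cells and 1 female cell. A ceiling-like LEC sub-cluster with 87 WT cells and 1 KO-labelled cell held 75 male and 0 female cells, and a floor-like one with 22 WT cells and 0 KO-labelled cells held 15 male and 0 female cells. The nodes of each genotype were pooled, so how many animals these cells came from was not analysed here.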
